A study of Homo sapiens with 6 samples.

How the data were processed

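Gene expression was measured by RNA sequencing in 6 libraries of an acute myeloid leukaemia cell line, 3 treated with vehicle and 3 with 1 µM ALRN-6924 for 6 h. The titles give each library its group and replicate number. Per the submitters' processing notes, the tools used were Trim Galore, FastQC, STAR, Picard and DESeq 2.0, with the hg19 genome build. Their order, settings and other versions, and the gene annotation release, are not given in the sources used here.

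For each library the authors deposited a table of read counts per gene in the layout that STAR writes, with 1 count for no strand and 1 for each strand. These counts are whole numbers and not normalized. A table of regularized log2 values (rlog) for 10966 genes was also deposited by the authors, with 1 column per library, along with the position of 1 transcript per gene. The authors' deposited table of the comparison gives, per the file header, a mean normalized signal over libraries, a log2 fold change with its standard error, and p-values with an adjusted p-value, for the genes past the authors' threshold.

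The counted strand was chosen by a rule fixed before the data were examined: a strand holding over 80% of the stranded reads in every library. The strand opposite to the read held 93.8% to 94.7% and was used. Because the count uses strand, a gene and its antisense partner are counted apart, but genes that overlap on 1 strand lose shared reads as ambiguous. Rows that name no gene stayed out of library sizes and tests. They held 1.47% to 2.32% of each table's total as unmapped, 11.8% to 15.7% as multi-mapping, 22.2% to 27.7% as reads in no gene and 1.77% to 2.04% as ambiguous reads. Multi-mapping reads were not counted, so levels of genes with near-identical copies, such as ribosomal protein genes, are uncertain.

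Of 60259 genes counted, 15158 passed edgeR's filterByExpr (minimum count 10, minimum total count 15). They were tested with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood fit, two-sided test, treatment as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. With 20752237 to 35015212 reads in genes per library, the common biological coefficient of variation was 12.3%. Gene symbols came from the authors' deposited tables for 10965 tested genes and from the reference name table for 2812. Gene types, GC content and transcript length came from GENCODE 29. Positions are hg19 transcript spans from the authors' deposited table. Its starts were read as counted from 0 and are given here counted from 1. End minus start equalled the length of the same transcript in GENCODE for 4087 of 10863 transcripts, and end minus start plus 1 did so for 74.

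The fit was tested on simulated counts with the real genes' means and library sizes and the same spread in every gene. Only genes above a low mean level were changed. No library of low complexity and no effect shared by replicate number was simulated. The rates that follow are those of the simulated counts and do not carry over to the real libraries. Among 15101 genes, 61.2% of the genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 7 of 181 calls were false.

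Gene lists were fixed before the data were examined: 6 lists of p53 targets (arrest, apoptosis, feedback, DNA repair, metabolism and autophagy, and other direct targets), cell cycle lists (G1/S and DNA replication, G2/M and mitosis), ribosome lists (MYC and ribosome biogenesis, cytosolic ribosomal proteins), stress and metabolic lists, survival genes, and markers of myeloid cells and of other cell types, 30 in all. The leukaemia list with KMT2A rearrangement in its name was chosen because the spelling of the line is close to that of MOLM-13, which carries such a rearrangement. For each list, members past the threshold were counted over all tested genes and adjusted over the list alone. The 28 lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. With the estimated correlation, 5 of the 6 p53 lists held, and the p53 feedback, G1/S, G2/M, MYC and ribosomal protein lists did not. The camera adjusted p also rose where the estimate was near the preset, from 1.87e-26 to 0.0189 for other direct p53 targets (estimate 0.021). For the monocyte and macrophage markers (estimate -0.048) it rose from 0.0552 to 0.278. A lost call is therefore not put down to correlation between genes alone. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, was an alternative. MRC1, a member of the monocyte list, was not analysed here.

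The rule for named genes, also set before the data were examined, was as follows. MDM2, MDM4 and CDKN1A are always named. The 12 largest rises and 12 largest falls are named among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups. Up to 4 tested members of each list with the smallest p are named too. Genes outside this rule are marked as named after their values were seen. A list or gene that is not called has no direction, so a change of sign in it was not counted as a reversal.

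The alternatives were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in 3 libraries, the unstranded count, the replicate number as a block, limma on the authors' deposited rlog values, leaving out each library, a minimum fold of 1.5, and an adjusted p under 0.01. A correction of each library for GC content and transcript length was added after the data were seen. An adjusted p that DESeq2 gave as NA stayed NA. Figures were drawn with matplotlib from the tables of results.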

Results

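RNA sequencing was used to measure gene expression in an acute myeloid leukaemia cell line, spelled Moml13 in the labels and abbreviated M13 in the deposited tables. The cells were treated for 6 h with vehicle (DMSO) or with 1 µM ALRN-6924. The series title names inhibition of both HDM2 and HDMX as its subject. HDM2 and HDMX are the proteins of MDM2 and MDM4, which bind the tumour suppressor p53 and keep its activity low. There were 3 libraries per group, and the comparison asks how the transcriptome differed after 6 h with the compound. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

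The vehicle libraries held 35015212, 30900326 and 22093863 reads assigned to genes and the ALRN-6924 libraries 26792439, 20752237 and 23515742. ALRN-6924 replicate 3 stood apart, with at least 1 read in 20141 genes against 23349 to 24545 in the other 5 libraries. Every pair of libraries of a group differed by more than counting noise, so all were counted as separate samples.

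After ALRN-6924, genes known to be activated by p53 rose together, and many genes used for entry into S phase and for DNA replication fell. Of 89 tested members of 6 lists of p53 targets, 56 rose, 0 fell and 33 did not pass the test. MDM2, itself a p53 target, rose 4.83-fold, from 379 ± 38.7 to 1835 ± 354 CPM (reads of a gene scaled to a common library size; mean ± SD, n = 3 per group). CDKN1A, which encodes the cell cycle inhibitor p21, rose 7.35-fold, from 133 ± 23.0 to 975 ± 31.2 CPM. Of 30 G1/S and DNA replication genes, 19 fell, 0 rose and 11 did not pass, and the call of that list was lost with an estimated correlation between genes (adjusted p = 0.172).

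In the whole transcriptome, 300 of 15158 tested genes were higher in ALRN-6924 and 185 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises were larger than the falls. The median log2 fold change was 0.90 among the higher genes and -0.55 among the lower genes, and 131 rises but 13 falls were at least 2-fold. For all 485 called genes the 3 libraries of one group did not overlap the 3 of the other. Such separation was seen in 24.9% of tested genes, where chance gives 10%.

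The number of calls depended on single libraries, on the tool, on the filter, on a block for replicate number and on a correction for gene content. It was largest with the replicate block (1345 higher, 1824 lower) and with no filter on low counts (636 higher, 733 lower). It was 161 higher and 87 lower without vehicle replicate 1, 160 and 52 without vehicle replicate 2, 134 and 44 without ALRN-6924 replicate 2, and 238 and 115 without ALRN-6924 replicate 3. The share of calls that were higher was 61.9%, against 44.9% (391 higher, 480 lower) after a correction for GC content and length chosen after the data were seen, and 45.3% (446 higher, 539 lower) with DESeq2. Across 5 equal groups of genes ordered by GC content, the median log2 fold change went from -0.16 at the lowest GC to 0.17 at the highest.

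**Figure D1:**
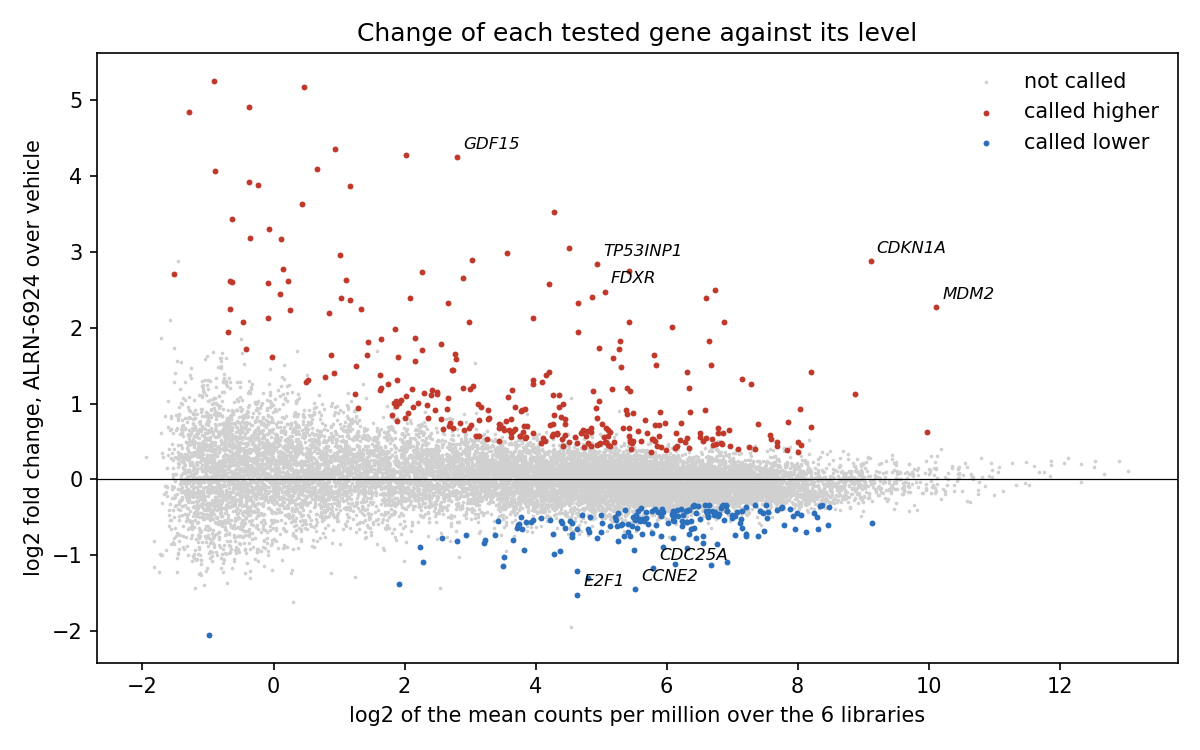
Log2 fold change of ALRN-6924 over vehicle (vertical axis) against the log2 of the mean CPM over the 6 libraries (horizontal axis), 1 point per tested gene, with the 300 genes called higher in red and the 185 called lower in blue. The rises reach further from 0 than the falls, with CDKN1A and MDM2 at log2 fold changes of 2.88 and 2.27 and E2F1 at -1.52.

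Genes of the pathway that the compound is directed at were read first. MDM2 (ENSG00000135679.21, hg19 chromosome 12, 69201952 to 69244466, plus strand) had a log2 fold change of 2.27 ± 0.14 (SE) with an edgeR adjusted p of 1.55e-05. CDKN1A (ENSG00000124762.13, hg19 chromosome 6, 36644237 to 36655116, plus strand) had a log2 fold change of 2.88 ± 0.12 and an edgeR adjusted p of 1.40e-06. MDM4 (ENSG00000198625.12, hg19 chromosome 1, 204485507 to 204527248, plus strand) was at 249 ± 9.60 CPM in vehicle and 253 ± 24.3 CPM in ALRN-6924, with a log2 fold change of 0.03 ± 0.09 and an edgeR adjusted p of 0.892. The positions are transcript spans from the authors' deposited table, and the reads were counted over the exons of each gene.

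**Figure D2:**
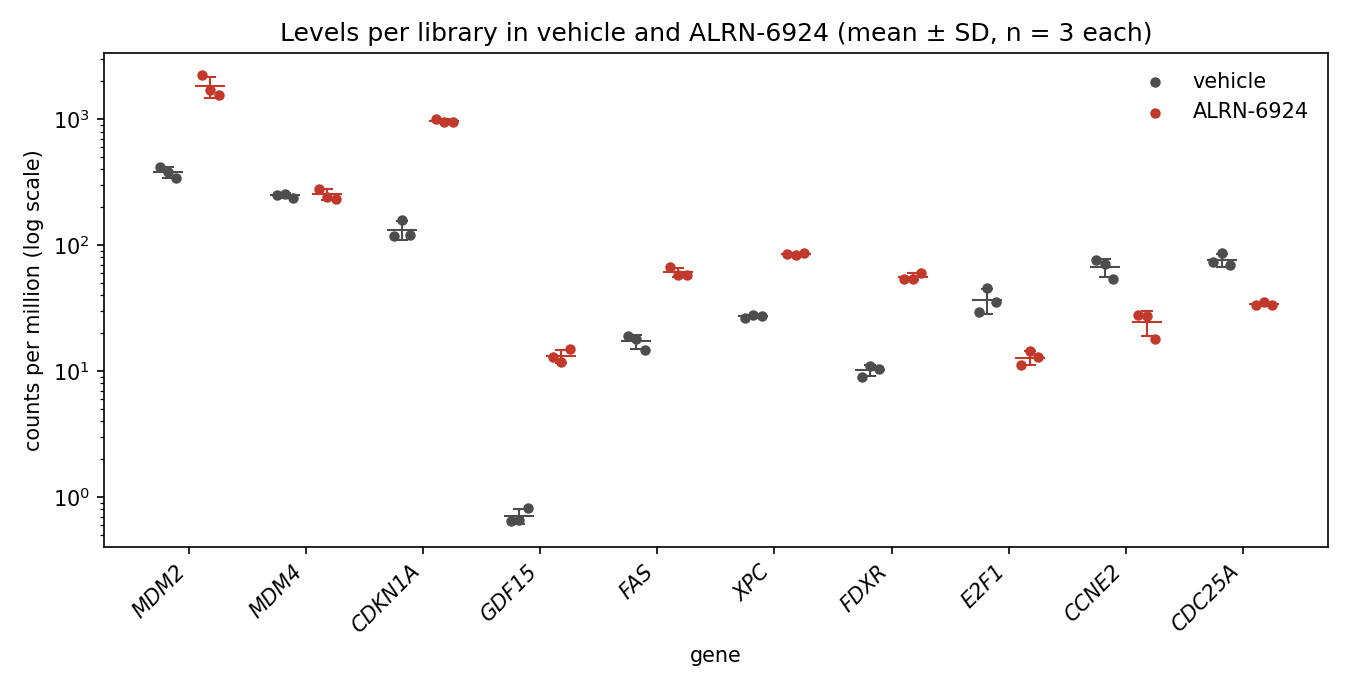
CPM on a log axis for 10 genes in the 3 vehicle libraries (grey) and the 3 ALRN-6924 libraries (red), 1 point per library, with the mean and SD of each group as horizontal bar and whiskers. MDM2, CDKN1A, GDF15, FAS, XPC and FDXR lie higher in every ALRN-6924 library than in any vehicle library, E2F1, CCNE2 and CDC25A lie lower, and MDM4 stays near 250 CPM.

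Among p53 targets that hold the cell cycle, 7 of 9 tested genes rose (9 adjusted over the list alone), with a median log2 fold change of 1.95. The limma camera test of the list gave an adjusted p of 9.38e-16, and 0.0412 with an estimated correlation between genes. PLK2, a stress-induced polo-like kinase, rose from 9.21 ± 0.22 to 48.8 ± 2.26 CPM. GADD45A, a growth arrest gene induced by DNA damage, rose from 8.29 ± 0.51 to 41.7 ± 3.69 CPM. GDF15, a secreted stress cytokine, showed the largest fold among genes of at least 5 CPM on average, from 0.70 ± 0.10 to 13.2 ± 1.61 CPM. The members that did not pass, named after their values were seen, were E2F7 and PRDM1, with log2 fold changes of 0.38 and 0.39.

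Of the p53 targets that promote apoptosis, 10 of 13 tested rose (11 adjusted over the list alone). Their median log2 fold change was 1.41, with a limma camera adjusted p of 3.35e-14, and 0.0341 with an estimated correlation. BAX, which permeabilises the outer mitochondrial membrane, rose 2.66-fold to 115 ± 2.43 CPM. FAS, a death receptor, rose 3.54-fold to 61.2 ± 5.36 CPM. TP53INP1 rose 7.16-fold to 53.7 ± 10.5 CPM and PHLDA3, an inhibitor of AKT, rose 6.70-fold to 75.0 ± 3.03 CPM. PMAIP1, TNFRSF10A and APAF1, named after their values were seen, did not pass the test, with log2 fold changes of -0.20, 0.30 and -0.07.

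Of 6 DNA repair targets of p53, 5 rose (5 adjusted over the list alone), with a median log2 fold change of 1.42, a limma camera adjusted p of 1.68e-06 and one of 0.0442 with an estimated correlation. They included the nucleotide excision repair genes XPC, from 27.2 ± 0.66 to 85.0 ± 1.75 CPM, and DDB2, from 26.9 ± 3.75 to 108 ± 5.19 CPM. POLH, the translesion polymerase eta, rose 2.84-fold, and RRM2B, a ribonucleotide reductase subunit, rose 2.51-fold. FANCC, named after its value was seen, was at a log2 fold change of -0.22 and did not pass. Among regulators that feed back on p53, 3 of 6 rose (3 adjusted over the list alone). They were MDM2, ZMAT3 (3.53-fold) and the phosphatase gene PPM1D (1.81-fold). CCNG1, RCHY1 and COP1, the last 2 named after their values were seen, were at 0.37, -0.28 and -0.08 and did not pass. The camera adjusted p of the feedback list was 0.00697, and that call was lost with an estimated correlation (adjusted p = 0.564).

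Of 13 tested p53 targets in metabolism and autophagy, 7 rose (11 adjusted over the list alone), with a median log2 fold change of 0.45, a limma camera adjusted p of 1.87e-11 and one of 0.0341 with an estimated correlation. FDXR, a mitochondrial ferredoxin reductase, rose 5.56-fold and SESN1, a stress-induced inhibitor of mTORC1 signalling, rose 5.23-fold. SESN2 and TIGAR, a regulator of glycolysis, rose 2.31-fold and 2.29-fold. In the list of other direct p53 targets, 24 of 42 rose (34 adjusted over the list alone), with a median log2 fold change of 0.81, a limma camera adjusted p of 1.87e-26 and one of 0.0189 with an estimated correlation. TRIM22, an antiviral TRIM protein, rose 4.20-fold to 189 ± 10.5 CPM. CYFIP2 rose 4.23-fold, the zinc finger gene ZNF79 2.48-fold and the long non-coding RNA PVT1 2.25-fold.

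The 12 largest rises among genes of at least 5 CPM also held genes outside the 6 p53 lists. Absence from these lists does not mean that a gene is not a p53 target. MIR34AHG, the host transcript of the microRNA miR-34a (hg19 chromosome 1, 9208070 to 9257042, minus strand), rose 11.5-fold to 35.9 ± 3.03 CPM. IL21R, the interleukin-21 receptor gene (chromosome 16, 27413483 to 27463363, plus strand), rose 8.30-fold to 40.6 ± 1.99 CPM. The non-coding RNAs LINC01021 and GAS6-AS1 rose 7.89-fold and 7.44-fold. CSPG4, a membrane chondroitin sulfate proteoglycan (chromosome 15, 75966663 to 76005189, minus strand), was the most abundant of these after CDKN1A, from 32.1 ± 4.54 to 181 ± 8.79 CPM. FAT1, an atypical cadherin, rose 5.94-fold and ACTA2, smooth muscle actin, rose 6.33-fold. ACTA2 overlaps the start of FAS on the opposite strand, so the separation of their reads rests on the strand-specific count. The edgeR adjusted p of these 12 genes lay between 1.40e-06 and 0.0001004.

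Of the 30 G1/S and DNA replication genes, all of which were tested, 19 fell and 0 rose (26 fell adjusted over the list alone). The median log2 fold change was -0.57 with a limma camera adjusted p of 4.91e-20. That call was lost in the camera test with an estimated correlation (adjusted p = 0.172, estimate 0.385). The estimate alone was not shown to be the reason. E2F1, a transcription factor for S phase genes (ENSG00000101412.12, hg19 chromosome 20, 32263489 to 32274210, minus strand), fell from 36.8 ± 8.14 to 12.8 ± 1.67 CPM, a log2 fold change of -1.52 ± 0.17 with an edgeR adjusted p of 0.000906. CDC25A, a phosphatase that activates cyclin-dependent kinases, fell from 76.5 ± 8.91 to 34.04 ± 1.02 CPM. The replication factors MCM10 and CDC6 were 1.81 and 1.87 times lower.

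The 12 largest falls among genes of at least 5 CPM included 5 members of the G1/S list. After E2F1, the cyclin gene CCNE2 had a log2 fold change of -1.45 ± 0.18, E2F2 one of -1.21 ± 0.14, and the cyclin gene CCNE1 one of -1.03 ± 0.16. Outside the list, ZNF367 was 2.46 times lower, DTL, an adaptor of a replication-linked ubiquitin ligase, was 2.19 times lower, and UNG, uracil-DNA glycosylase, was 2.17 times lower. MSH6, a mismatch repair gene, fell from 165 ± 15.3 to 78.0 ± 5.52 CPM and KLHL23 was 1.93 times lower. KLF11 and PAQR4 were 2.21 and 1.98 times lower. Their calls were lost without ALRN-6924 replicate 2 (edgeR adjusted p 0.127 and 0.1001), KLF11 also without ALRN-6924 replicate 3 (0.106) and PAQR4 also without vehicle replicate 2 (0.0807) and with the unstranded count (0.141).

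Of 35 G2/M and mitosis genes, 2 fell and 0 rose (2 fell adjusted over the list alone), and the median log2 fold change was -0.13. The limma camera adjusted p was 0.000594, and the call was lost with an estimated correlation (adjusted p = 0.564). Both called genes were at the edge of the threshold. CCNA2, cyclin A2, had a log2 fold change of -0.51 ± 0.10 (edgeR adjusted p 0.0284) and the kinesin gene KIF11 one of -0.35 ± 0.07 (0.0318). Without single libraries the adjusted p reached 0.154 for CCNA2 and 0.151 for KIF11, in both without ALRN-6924 replicate 2. With the GC and length correction the list's median was -0.08 and KIF11 was at -0.17 (adjusted p 0.283). PRC1 and BUB1B were at -0.25 and -0.25 and did not pass.

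No single gene of the 2 ribosome lists passed the edgeR test. Of 32 MYC and ribosome biogenesis genes, 0 were called (2 lower adjusted over the list alone; 10 lower at an unadjusted p under 0.05 and 3 lower with DESeq2). Their median was -0.11, with a limma camera adjusted p of 0.0119, and 0.778 with an estimated correlation. The call was also lost without vehicle replicate 3 (adjusted p 0.104) and without ALRN-6924 replicate 1 (0.245, median -0.06). NIP7 and DDX21, a nucleolar helicase, were at -0.42 and -0.30, and NOLC1 and TSR1 at -0.23 and -0.23. Of 43 cytosolic ribosomal proteins, 0 were called (0 adjusted over the list alone; 6 higher at an unadjusted p under 0.05 and 1 higher with DESeq2). Their median was 0.13, with a limma camera adjusted p of 0.00208, and 0.838 with an estimated correlation. That median was 0.09 without ALRN-6924 replicate 2 (adjusted p 0.0917), 0.09 without ALRN-6924 replicate 3 and 0.07 with the GC and length correction. RPS19, RPL13, RPS9 and RPLP2 were at 0.32, 0.31, 0.23 and 0.22, and reads shared with ribosomal pseudogenes were left out of the counts as multi-mapping.

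**Figure D3:**
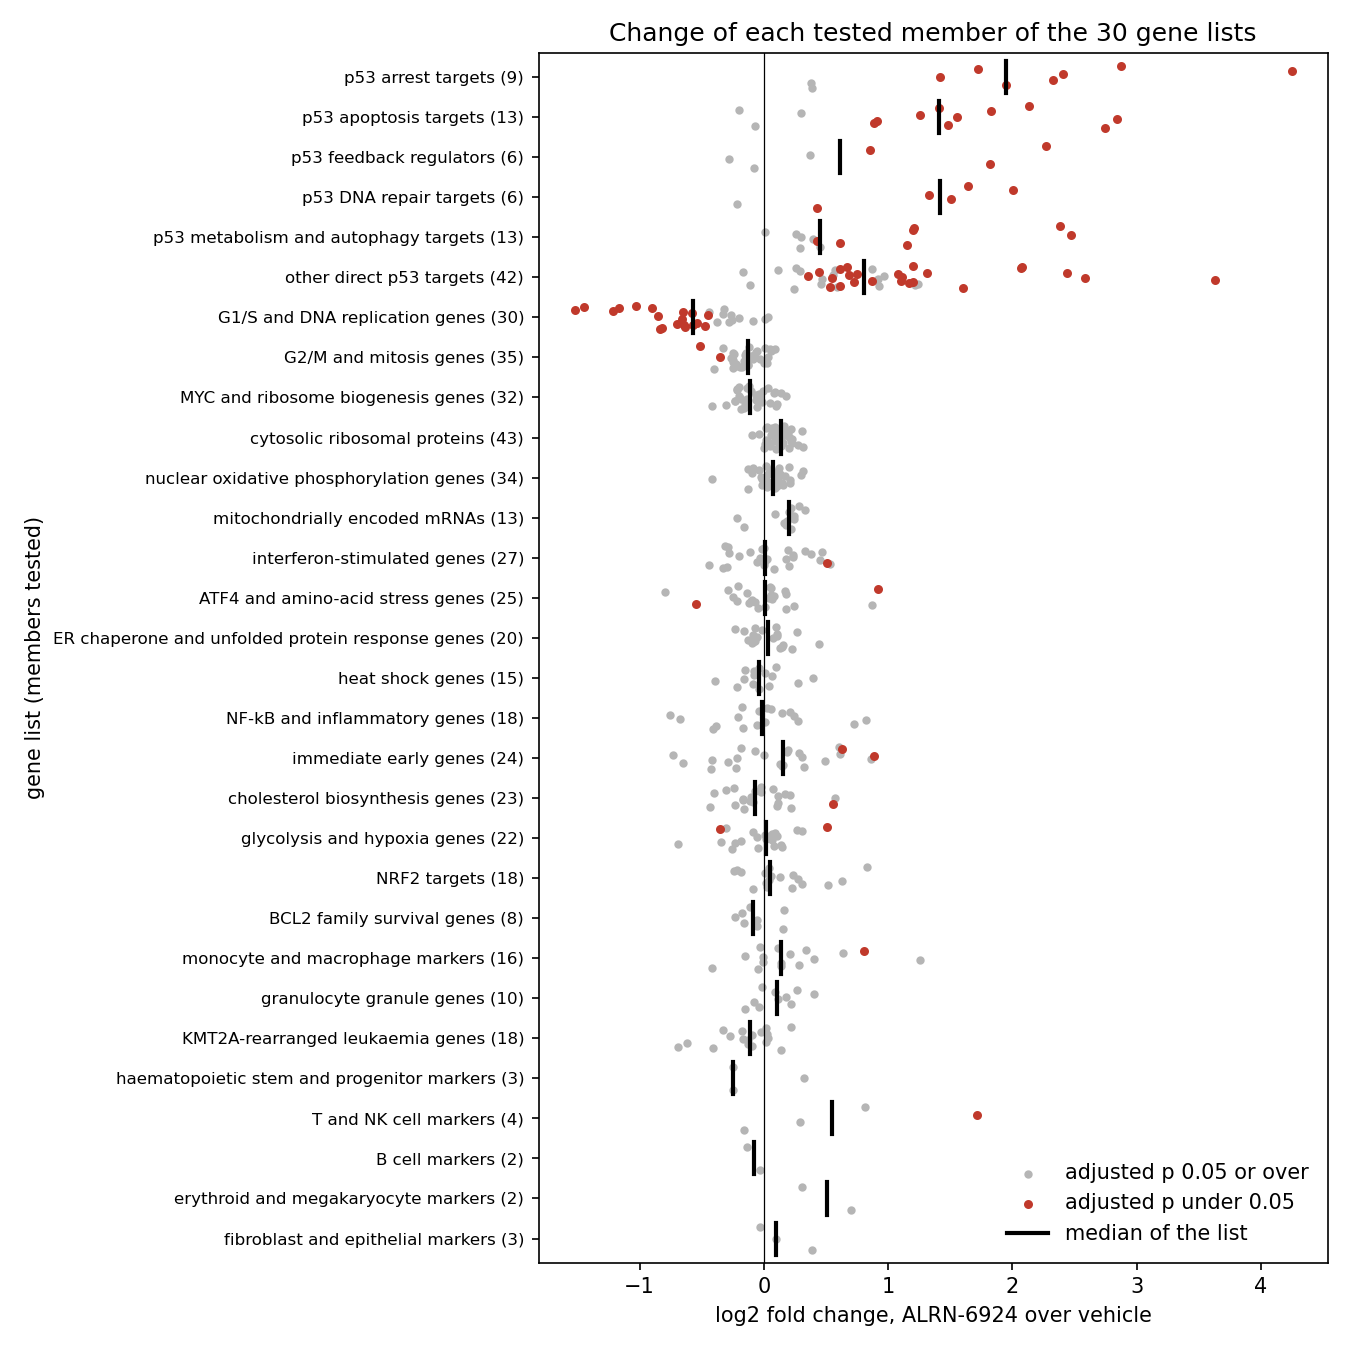
Log2 fold change of ALRN-6924 over vehicle for each tested member of the 30 gene lists, 1 point per gene, red where the edgeR adjusted p was under 0.05, with a black bar at the median of each list and the number of tested members beside its name. The 6 p53 lists lie to the right of 0 with medians from 0.45 to 1.95, the G1/S list lies to the left with a median of -0.57, and the other lists have medians between -0.24 and 0.55.

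Stress pathways other than that of p53 were not called as lists. The ATF4 and amino-acid stress genes had a camera adjusted p of 0.833. Their median and mean lay just above 0 (0.01 and 0.002) and the camera test pointed down. In it DDIT4, an inhibitor of mTORC1 signalling, rose from 181 ± 13.4 to 343 ± 10.3 CPM, and STC2 fell, with a log2 fold change of -0.55 ± 0.12 (1 higher and 1 lower of 25, also adjusted over the list alone). SLC3A2 and TRIB3 were at -0.22 and -0.29. At an unadjusted p under 0.05, 3 members of the ATF4 list were higher and 6 lower. With the GC and length correction 1 was called higher and 5 lower, and with DESeq2 1 higher and 1 lower. The ER chaperone and unfolded protein response list had an adjusted p of 0.625 and a median of 0.03, and the heat shock list one of 0.625 and -0.04. In these lists 0 genes were called by edgeR or DESeq2 (0 adjusted over each list alone), and at an unadjusted p under 0.05 there were 3 of 20 higher and 0 of 15. CRELD2, SDF2L1, SYVN1 and HYOU1 were at 0.45, 0.26, 0.23 and 0.15, and HSPB1, HSPD1, HSP90AA1 and BAG3 at 0.40, -0.16, -0.15 and 0.27. Without vehicle replicate 2 the heat shock list was called (median -0.13, adjusted p 0.0404).

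The interferon-stimulated list was not called (median 0.01, adjusted p 0.594), with STAT2 the 1 higher gene of 27 (also 1 adjusted over the list alone), at a log2 fold change of 0.51 ± 0.10. EIF2AK2, IRF7 and RSAD2 were at -0.32, 0.46 and 0.53. The NF-kB and inflammatory list had a median of -0.02 and an adjusted p of 0.765, with 0 of 18 called by edgeR (0 adjusted over the list alone, 1 higher and 3 lower at an unadjusted p under 0.05, and 1 lower with DESeq2). SOD2, CD83, TRAF1 and CXCL2 were at -0.41, -0.39, 0.73 and -0.68. Of the 24 immediate early genes, 2 rose (2 adjusted over the list alone), IER5 by 1.85-fold and FOSL1 by 1.55-fold, and the list was not called (median 0.15, adjusted p 0.349). DUSP4 and DUSP6 were at 0.86 and 0.49. The edgeR calls of STC2, STAT2 and FOSL1 were each lost without ALRN-6924 replicate 2 and without other single libraries, with adjusted p up to 0.130, 0.115 and 0.152.

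Metabolic lists were not called either. In the cholesterol biosynthesis list (median -0.07, mean -0.02, adjusted p 0.594), HSD17B7 was the 1 called gene of 23, with a log2 fold change of 0.55 ± 0.12, while INSIG1, IDI1 and SQLE were at -0.43, -0.40 and -0.31 and were called lower adjusted over the list alone (1 higher and 3 lower). In the glycolysis and hypoxia list (adjusted p 0.765), SLC2A1, a glucose transporter, rose 1.42-fold and HK2, hexokinase 2, was 1.28 times lower (2 higher and 2 lower adjusted over the list alone). Its median was 0.01, while its mean was -0.03 and the camera test pointed down. PDK1 and PFKFB3 were at -0.35 and 0.27. The edgeR calls of HSD17B7, SLC2A1 and HK2 were lost without each of several single libraries, with adjusted p up to 0.199, 0.137 and 0.141. The NRF2 target list (median 0.05, adjusted p 0.304) had 0 of 18 genes called by edgeR (0 adjusted over the list alone, 3 higher and 1 lower at an unadjusted p under 0.05, 1 higher with DESeq2), with FTH1, FTL, TKT and TXNRD1 at 0.52, 0.30, 0.28 and -0.18. Nuclear oxidative phosphorylation genes (median 0.08, adjusted p 0.273) had 0 of 34 called by edgeR and DESeq2 (0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05), with CYC1, NDUFS7, SDHD and NDUFV1 at 0.21, 0.30, -0.41 and 0.17.

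The mitochondrially encoded mRNAs had a median of 0.20 and a camera adjusted p of 0.179, with 0 of 13 called by edgeR and DESeq2 (0 adjusted over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05). MT-CO1, MT-ND3 and MT-ND1 were at 0.24, 0.33 and 0.28 and MT-ND6, the one encoded on the light strand, at -0.21. The list was called higher without vehicle replicate 3 (median 0.33, adjusted p 0.0146), without ALRN-6924 replicate 1 (0.30, 0.0352) and with the GC and length correction (0.25, 0.0316). The BCL2 family survival genes were not called (median -0.08, adjusted p 0.765). Among them 0 of 8 passed edgeR, adjusted over the list alone too, 0 passed DESeq2 and 0 passed an unadjusted p under 0.05. CFLAR, MCL1, BCL2L2 and BCL2L1 were at 0.15, -0.23, -0.18 and 0.16.

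The monocyte and macrophage list had a median of 0.14 and a camera adjusted p of 0.0552 (0.278 with an estimated correlation), with 1 of 16 tested genes higher with edgeR (3 adjusted over the list alone) and 4 higher with DESeq2. The edgeR gene was ITGAM, the integrin CD11b, which rose from 7.12 ± 0.08 to 12.5 ± 1.62 CPM. Its edgeR adjusted p was 0.0104, and 0.0517 and 0.0569 without vehicle replicate 2 and without ALRN-6924 replicate 2. CX3CR1, ITGAX and VCAN were at 0.40, 0.64 and 1.26. The list was called without vehicle replicate 1 (adjusted p 0.0145), without vehicle replicate 2 (0.0139), with the GC and length correction (0.0324) and with the fry test (0.00506). The granulocyte granule list (median 0.10, adjusted p 0.554) had 0 of 10 called by edgeR (0 adjusted over the list alone, 1 higher at an unadjusted p under 0.05 and with DESeq2), with AZU1, ELANE, RNASE2 and CTSG at 0.40, 0.26, 0.22 and 0.17. The list of genes linked to KMT2A-rearranged leukaemia (median -0.11, adjusted p 0.0815) had 0 of 18 called by edgeR (0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05 and 3 lower with DESeq2). HOXA9, HMGA2, MEF2C and RUNX2 were at -0.33, -0.41, -0.27 and -0.62.

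Markers of other lineages were mostly too low to test. Of 14 stem and progenitor markers 3 were tested, MLLT3, GATA2 and MN1, at -0.24, -0.25 and 0.33 (adjusted p of the list 0.787). Of 17 T and NK cell markers 4 were tested (median 0.55, adjusted p 0.0942). PRF1, the perforin gene, rose within a very low range, from 0.36 ± 0.17 to 1.14 ± 0.07 CPM (1 higher, 2 adjusted over the list alone), and its edgeR adjusted p of 0.0475 reached 0.211 without vehicle replicate 2, while with library totals alone it was 0.0500334. TRAC, NKG7 and NCAM1 were at 0.81, 0.29 and -0.16, and the list was called without vehicle replicate 2 (adjusted p 0.0395). The B cell list and the erythroid and megakaryocyte list had 2 tested members each, too few for a list test, PAX5 and BANK1 at -0.13 and -0.03 and EPOR and GP9 at 0.31 and 0.70. In the fibroblast and epithelial list (adjusted p 0.594), MUC1, KRT8 and COL1A1 were at 0.39, 0.10 and -0.03. In the stem, B cell, erythroid and fibroblast lists 0 genes were called by edgeR or DESeq2 (0 adjusted over each list alone), and at an unadjusted p under 0.05 there was 1, in the fibroblast and epithelial list.

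The authors' deposited table of this comparison lists 954 genes past its own threshold, 472 higher and 482 lower. Of these, 953 were tested here, all 953 had the same direction as in the authors' deposited table, and 471 were also called here. A further 14 genes were called here and are not in the authors' deposited table. The authors' deposited table gives log2 fold changes of 2.03 for MDM2, 2.61 for CDKN1A and -1.33 for E2F1, and MDM4 is not among its genes. The settings behind these fold changes are not given in the sources used here, so their sizes are not compared with those from edgeR.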

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

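The correction for GC content and length, the counting interval of the marker test and the test of sense reads on the wrong strand were chosen only after the data had been seen.

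The strand that was not counted also held a signal. On it 23 of 9948 tested genes rose with ALRN-6924 by the edgeR test, and for 20 of them the gene's own strand was not called or was too low to test. The 5 with the smallest adjusted p were ENSG00000271730.1 (log2 fold change 2.66), CPM, the carboxypeptidase M gene (2.21), IL21R-AS1 (3.12), XPC-AS1 (1.72) and ENSG00000260892.1 (2.36). Of the 19 genes found in GENCODE 29, 18 (94.7%) overlap a gene annotated on the other strand, and 16 overlap a gene called higher there, such as MDM2, IL21R, XPC, SESN1 or CSPG4. Levels were also compared for sense reads put on the wrong strand. The genes were picked for a rise without a call on their own strand, which by itself leaves out most of such a leak. The ratios below therefore describe the genes and do not decide the question. In 16 of the 20 genes the other strand was above the own strand in ALRN-6924, and the lowest ratio of other to own strand, in GTPBP2, was 0.206 (95% counting interval 0.192 to 0.222) against at most 0.0663 for all genes together. For the 16 genes that overlap a gene called higher, the likely source is reads of those neighbours. The share of overlap among all 9948 tested genes was not counted. WDR24 and PLEKHG1 overlap genes whose symbols matched no gene called higher, MPP2 overlaps none, and ENSG00000268427.1 was not found in GENCODE 29. The match was by gene symbol, which can differ between annotations, so a called neighbour may have been missed. The source of the reads in these genes stays open, and no separate regulation of the 20 genes is claimed.

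ALRN-6924 replicate 3 stood apart from the other 5 libraries by its low number of genes with a read. Lower depth is argued against, since after thinning all libraries to the smallest total it still had 2884 genes fewer than the lowest other library (19988 against 22872). A weaker response is argued against, as the median log2 ratio of p53 targets in it lay 0.0367 from the mean of the other ALRN-6924 libraries (0.89 against 0.93 and 0.78). What fits is a library made from fewer distinct RNA molecules: among genes expected at 10 to 20 reads, 6.08% had 0 reads against at most 0.398% elsewhere, a ratio of 15.3, and single reads were rarer (23.0% of genes with 1 to 10 reads against 34.7% to 37.5%). The marker sums do not decide on RNA from another cell type. The erythroid and megakaryocyte sum was highest there (17.6 against at most 12.3 CPM, a ratio of 1.43 with a 95% counting interval of 1.23 to 1.68, which reaches past 1.5, the bound set before the test), but 14.7 of its 17.6 CPM came from EPOR, which was at 9.28 to 10.7 CPM in the other libraries. The fibroblast and epithelial sum was also highest (42.5 against at most 33.8 CPM, a ratio of 1.26), with 40.9 CPM from MUC1 alone, while KRT8 and COL1A1 were not raised. The T and NK and the B cell markers were not highest there (ratios 0.859 and 0.921). No other biological explanation was tested.

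The fall of G1/S and DNA replication genes was set against 2 technical explanations, because gene changes followed GC content. If GC or length bias made it, correcting for them would shrink it, yet with the GC and length correction, which used values for all 30 members, the median log2 fold change was -0.60 against -0.57 before it. ALRN-6924 replicate 3 is not its source alone, since the median was -0.60 without that library. A response to ALRN-6924 stays open as a hypothesis. The list was fixed before the data were examined, but its fall was seen and set against these explanations on the same 6 libraries. Its camera call was lost with an estimated correlation between genes (adjusted p = 0.172). The list was called with the fry test (adjusted p 0.00373). At the preset correlation it was also called when each library was left out (camera adjusted p at most 2.22e-14).

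Among the 10 ways to split the 6 libraries into 3 and 3, the real one called 485 genes and the highest of the others 2, so 1 split of 10 called as many. With 10 splits the share cannot fall under 0.05, and no more can be said from it.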

How the results depend on the processing

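The GC and length correction was chosen only after the data had been seen. No called list or named gene reversed under any alternative. Of 133 named genes 56 were called, and 44 of these kept their call under every alternative fit, tool and filter that gave them an adjusted p (the minimum fold and the stricter p were applied to gene counts only), among them MDM2, CDKN1A and E2F1. Of the 77 not called, 51 became called with the replicate block, 26 with no filter and 18 with DESeq2. The p53 arrest, apoptosis, DNA repair, metabolism and other target lists were called under every alternative. Of 266 values of uncalled lists, 31 had a median of the other sign. The median log2 fold change of all genes was 0.00187, and 0.0222 with library totals alone.

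The count of higher genes (300) was 636 with no filter on low counts, 89 with a minimum fold of 1.5, 141 at an adjusted p under 0.01, and 134 to 294 when each replicate was left out. The count of lower genes (185) was 539 with DESeq2, 733 with no filter, 480 with the GC and length correction, 8 with the minimum fold, 49 at the stricter p, and 44 to 238 when each replicate was left out. The minimum fold and the stricter p lower such counts by construction, and the cause of the other shifts was not tested. All 485 called genes were also called with no filter, 456 with DESeq2, 443 with the correction and 319 without ALRN-6924 replicate 3.

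With an estimated correlation the calls of the feedback (median 0.61), G1/S (-0.57), G2/M (-0.13), MYC (-0.11) and ribosomal protein (0.13) lists were lost, and with fry those of the G2/M (-0.13, adjusted p 0.137), MYC (-0.11, 0.258) and ribosomal protein (0.13, 0.290) lists. When each replicate was left out the median was -0.136 to -0.0623 for the MYC list, 0.0867 to 0.172 for ribosomal proteins, 0.0915 to 0.332 for mitochondrially encoded mRNAs, -0.131 to 0.0184 for heat shock, 0.10 to 0.19 for monocyte and macrophage markers and 0.50 to 0.68 for T and NK markers, each crossing the threshold at least once. The mitochondrially encoded list became called with the GC and length correction (0.25). The monocyte and macrophage list became called with no filter (0.13), at 1 CPM or more (0.15), with limma on the authors' rlog values (0.0627), with the correction (0.0836) and with fry (0.14), and the T and NK list with fry (0.55). The cause of these changes was not tested.

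Replicate numbers were checked for pairing. Deviations from the group means correlated at 0.37, 0.03 and 0.22 across genes for numbers 1, 2 and 3, and at 0.80, 0.08 and 0.67 among the 4548 genes of at least 50 CPM. Not every pair was over 0.1, the bound set for pairing, so the main fit treats the samples as sharing only a number. The low value of number 2 does not argue against pairing. Deviations from a mean of 3 libraries sum to 0, so little is left for number 2 where numbers 1 and 3 pull apart. Across all tested genes every library correlated best with the library of its own number in the other group. For vehicle replicate 2 the margin was small, 0.0349 against 0.0287 for another ALRN-6924 library. This is a hint from the data and not the design. The slope of library levels on GC content also rose with the number, from -0.19 to 0.01 in vehicle and from -0.05 to 0.20 in ALRN-6924. With the replicate block 1345 genes were higher and 1824 lower, against 300 and 185 in the unpaired fit. If the numbers mark pairs, the unpaired fit counts their shared differences as spread, and some genes that did not pass may change.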

Other observations

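The genes in the first 2 paragraphs and the test of the TNF families were chosen only after the data had been seen.

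Non-coding RNAs were among the rises. Of 1462 tested long intergenic and antisense RNAs, 19 were higher and 2 lower, beside 264 higher and 180 lower of 11624 protein-coding genes. NEAT1, the scaffold RNA of nuclear paraspeckles, rose from 296 ± 51.9 to 645 ± 84.0 CPM, a log2 fold change of 1.13 ± 0.13 with an edgeR adjusted p of 0.00142. Of 8 tested plexin receptor genes 4 rose, 0 fell and 4 were not called. PLXNB2 rose from 161 ± 21.9 to 430 ± 45.1 CPM (edgeR adjusted p 0.000129) and PLXNB1 from 9.98 ± 1.72 to 24.3 ± 2.30 CPM. PLXNB3 and PLXNA2 rose within lower levels, to 4.07 ± 0.60 and 1.47 ± 0.21 CPM, while PLXNC1, PLXNA1, PLXNA3 and PLXND1 were at log2 fold changes of -0.31, 0.26, 0.27 and 0.07.

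These genes of DNA repair and checkpoints were picked one by one, and no set of them was tested. XRCC2, which acts in homologous recombination, had a log2 fold change of -0.93 ± 0.11 (edgeR adjusted p 0.00129). The checkpoint genes CHEK1 and CLSPN were at -0.75 ± 0.10 and -0.74 ± 0.10. BRCA1 was at -0.44 ± 0.08 (adjusted p 0.0191), and BRCA2, at -0.41 ± 0.13, was not called (adjusted p 0.127).

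TNFSF9 and CD70, ligands of the TNF superfamily, rose from 14.5 ± 0.96 to 48.2 ± 2.14 CPM and from 29.99 ± 4.91 to 85.0 ± 9.92 CPM. A hypothesis is that TNF ligand and receptor genes rise more often than other genes. Of 24 tested members 5 rose (these 2, FAS, TNFRSF10B and TNFRSF10D), an odds ratio of 13.2 (two-sided Fisher's exact test, p = 9.16e-05), but 3 of them are p53 targets by the lists. Outside the p53 lists 2 of 20 rose, an odds ratio of 6.80 with a 95% interval of 0.76 to 28.6 (Fisher's exact test, p = 0.0410). By a first rule, an odds ratio over 1 with p under 0.05, the hypothesis fitted. The rule was tightened after that result, because both genes had prompted the test and the interval includes 1, so the hypothesis stays undecided.

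The libraries also held RNAs that mostly lack a poly(A) tail. The small nuclear RNA RN7SK was at 3740 to 6520 CPM, and 72 histone genes together were at 6740 to 11086 CPM. Library levels also followed GC content to a different degree, with slopes from -0.19 to 0.01 (log2 per 10 percentage points of GC) in the vehicle libraries and from -0.05 to 0.20 in the ALRN-6924 libraries.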
